A study of Mus musculus with 14 samples.

How the data were processed

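Small RNA libraries from 8 exosome and 6 cell lysate samples were read from 1 table of counts per mature miRNA that the authors deposited for the whole series. Per the labels' protocols, culture supernatant was cleared by centrifugation, exosomes were purified on an OptiPrep density gradient, and libraries were made with the PerkinElmer NextFlex small RNA kit. Per the submitters' processing notes, cutadapt (no version given) and the mouse build mm10 were used; the aligner, the counting program, the miRNA annotation and whether strand was used are not given in the sources used here. The values are raw counts, as the name of the deposited table and its whole numbers show, with no normalization. Adapter trimming with cutadapt and the counting step set which reads reached a line, and neither could be changed here. PCR reads are not independent molecules, so intervals and floors cover counting error only.

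The table has 1250 lines, of which 10 join mature miRNAs of 1 sequence. Among lines with 10 or more counts, 8 equal another line in all 14 libraries, and near-copies share reads (miR-101a-3p had 64522 counts and miR-101c 64674). Members of the miR-378, let-7, miR-99/100 and miR-125 families, the overlapping miR-203 and miR-203b genes and other paralogs are therefore uncertain where the counting could split them. Each column was matched to its sample by the sample's title, and 0 columns were left unused. Groups were taken from the titles and treatment labels. The titles' dates gave replicate numbers 1 to 4 in exosomes (25 January, 16 March, 5 April and 29 December) and 1 to 3 in lysates (23 January, 14 March and 21 March). By the titles, 29 December is of the year before the other dates, so exosome replicate 4 is the earliest. No pair of libraries in a group was alike within sampling noise (smallest chi-square per degree of freedom 21.0), so all 14 were counted as separate libraries.

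Total counts ran from 28417 to 411671 in exosomes and from 3941480 to 6792079 in lysates. At the smallest total 1 read is worth over 30 CPM, so the precision of exosome values below some 100 CPM is limited by counting, while lysates resolve values well under 1 CPM. The biological coefficient of variation was 0.493 in exosomes, 0.350 in lysates and 0.480 over all 14 libraries.

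Differences between groups were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM factors, glmQLFit and glmQLFTest, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. IL4 was compared with control within exosomes (182 miRNAs tested) and within lysates (443), each fitted on its own libraries. Exosomes were compared with lysates in control and in IL4 samples, and the IL4 effects of the compartments with each other (338 miRNAs), in 1 fit of all 14 libraries. CPM are counts scaled to the library's total, whereas log2 fold changes are on the TMM scale. Standard errors are the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic, and confidence intervals were built from them. They therefore restate the test and are not a separate measure of spread. Where a lysate group had 0 counts, a fold was computed as the mean CPM of the exosome libraries over a floor of 3 counts over the group. Such a fold is a lower bound on the lysate side only, since the exosome mean is an estimate with its own spread. With 1 to 3 lysate counts the ratio is of counts pooled over each group, with a 95% counting interval. These kinds of fold are therefore not on the same scale.

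The tests, alternatives, lists and rules were fixed before the data were examined. In each comparison the text names, among miRNAs with an adjusted p at or under 0.05 and a mean of at least 10 CPM, the 10 largest rises and the 10 largest falls, the most abundant miRNAs, the 4 study-named ones, members of the fixed lists as examples and, where fewer than 5 were called, the 5 with the lowest unadjusted p. The 22 lists were the study-named miRNAs (known from the study, which picked them on these samples), miRNAs reported under IL4, the miR-378 family, inflammatory, cholesterol-related and haematopoietic miRNAs, the miR-17/92 cluster and its paralogs, the miR-99, let-7 and miR-125 clusters, the let-7 family, the miR-23/27/24 clusters, miR-221/222, miR-183/96/182, the Sfmbt2 and Dlk1-Dio3 clusters, miRNAs reported as released, and markers of erythroid, lymphocyte, stromal, endothelial, epithelial, muscle and liver, gut and serum origin. The erythroid markers miR-451a and the miR-486 line are also in the released list, miR-144-3p is also in the cholesterol-related list, and miR-150-5p is in the lymphocyte, released and haematopoietic lists. For 6 listed miRNAs no line was found, and they were not analysed here. Lists with at least 3 tested members were tested with limma 3.58.1's camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives, adjusted over lists. Calls within a list were also adjusted over the list alone.

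The share of reads per list, library totals, detected miRNAs (after thinning to 28417 counts) and the share of reads from the lower arm of 405 arm pairs were compared by exact permutation tests, two-sided, in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. The smallest p is 0.0286 for 4 against 4 or 4 against 3 libraries and 0.1 for 3 against 3, so the lysate comparison cannot reach 0.05 by these tests. Correlations across miRNAs used 100000 permutations. Figures were drawn with matplotlib 3.10.9.

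Same-date libraries deviated together from their group means in both compartments (r = 0.46, 0.19, 0.72 and 0.27 in exosomes and 0.61, 0.26 and 0.28 in lysates). Some pairs of different dates were as alike. The IL4 exosomes of 16 March and the controls of 5 April had r = 0.26, and the IL4 lysate of 14 March and the control of 21 March 0.32. Pairing by date is therefore clear for some dates only, and the date as a block was an alternative fit. The other alternatives were median-of-ratios, library-size and upper-quartile scaling, no filter, a filter at a mean of 10 CPM, DESeq2 1.42.0, limma voom, other sets of libraries in the fit, and leaving out each replicate. Among the analyses added after seeing the data were fits without the miR-203 lines, without the libraries of 25 January or of 23 January, with all libraries thinned, and list calls under each scaling.

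The tests were checked on simulated counts drawn from the real library sizes and the mean share of each line in its compartment. Libraries were drawn independently, with no date effect. The rates therefore do not cover the way in which same-date libraries deviated together. In each of 3 draws, 200 lines were changed by 2-fold or 4-fold. For exosomes against lysates the means were pooled over all 14 libraries, so the simulated compartments differed only in the changed lines. The rates for these comparisons therefore do not cover the wide difference between compartments in the real data. Recovery is given over the changed lines that passed the filter on low counts, not over all 200 changed in each draw. Over the draws, 541 exosome lines were tested, 32 of them changed by 2-fold and 47 by 4-fold. Of the 2-fold changes 21.9% and of the 4-fold changes 78.7% were recovered, with 0% of calls false. In lysates (1359 lines) it was 17.7% and 83.1%, with 4.48% false. For exosomes against lysates it was 9.09% and 56.4% in controls (1009 lines, 1.92% false) and 7.59% and 51.1% with IL4 (1057 lines, 1.89% false), and for the difference of effects 0% and 8% (1060 lines, 0% false).

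Genomic positions and host genes came from GENCODE vM21 on GRCm38, the build also named mm10, by miRNA gene name, with positions counted from 1; 471 of 500 tested lines matched at least 1 gene. Mature miRNAs made by several genes cannot be placed on 1 of them. An exon was named where it belonged to any annotated transcript of the host gene, so the site may be intronic in other transcripts.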

Results

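MicroRNAs (miRNAs) were profiled by small RNA sequencing in 14 mouse libraries with bone marrow as their source. Exosomes, small vesicles that cells release, gave 8 libraries, 4 from control macrophages and 4 from stimulated ones, and cell lysates gave 6, with 3 in each group. The titles of the stimulated libraries name IL4, a cytokine that drives macrophages towards an alternative, tissue-repairing state. Exosomes had been purified from culture supernatant on a density gradient. The titles also carry dates. Within a compartment each date held 1 IL4 and 1 control library, and no date was shared between exosomes and lysates.

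The exosome libraries were far shallower than the lysates. Total miRNA counts were 50032, 74646, 411671 and 76729 in IL4 exosome replicates 1 to 4, and 28417, 54381, 199025 and 36576 in control exosome replicates 1 to 4. Lysate totals were 5852831, 3941480 and 5137200 with IL4 and 5750888, 6792079 and 5511688 in controls. Between the groups as wholes, the total did not differ with IL4 by more than the spread between replicates (exact permutation test, two-sided, p = 0.486 in exosomes and p = 0.3 in lysates). Within dates, however, the IL4 exosome library had the higher total at 4 of 4 dates, by 1.37 to 2.10-fold (exact permutation of the within-date differences, two-sided, p = 0.125, the smallest that 4 pairs allow), and the IL4 lysate at 1 of 3 (p = 0.5, smallest possible 0.25). By the unpaired test exosomes lay below lysates in control and in IL4 samples (exact permutation p = 0.0286 for each, the smallest this design allows). Of 1250 mature miRNA lines, 331 to 510 had a count in an exosome library and 763 to 881 in a lysate. After every library was thinned to 28417 counts, a mean of 339 lines were detected in control exosomes against 251 in control lysates, and 329 against 246 with IL4 (exact permutation p = 0.0286 for each). Without thinning, lines with at least 10 counts were fewer in exosomes (difference -285.25 in controls and -219 with IL4). The most abundant miRNA was miR-21a-5p, a miRNA induced in many activated cells, at 247539 ± 56992 CPM (counts scaled to the library's total; SD, n = 4) in IL4 exosomes and 212538 ± 28889 in control exosomes. The labels do not say whether replicates came from separate animals or cultures, so p-values measure the spread between these libraries, which may be technical.

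The first comparison asked which miRNAs IL4 stimulation changed in the released exosomes, whose miRNA cargo is the subject of the series. The miRNA miR-146b-5p, a brake on Toll-like receptor and NF-kB signalling, was 3.14-fold higher in IL4 than in control exosomes (log2 fold change 1.65, SE 0.27, 95% confidence interval 1.03 to 2.27, 4 against 4 libraries). Its level was 3136 ± 1151 CPM with IL4 and 1096 ± 116 in controls, and it was higher at 4 of 4 dates. It was the 1 call among the miRNAs tested (14.6% of lines) with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment (adjusted p = 0.0296). Among the other miRNAs with the lowest unadjusted p, miR-99a-5p, which targets the growth regulator mTOR, had a log2 fold change of 0.80 (SE 0.21, adjusted p = 0.216), with 5391 ± 362 CPM against 3430 ± 635. For miR-378a-3p, encoded within the gene of the metabolic coactivator Ppargc1b, the value was 1.15 (SE 0.30, adjusted p = 0.216). For miR-223-3p, the myeloid miRNA that restrains granulocyte production and inflammasome activity, it was -0.75 (SE 0.20, adjusted p = 0.216), with 11143 ± 903 CPM against 20895 ± 5020, and it was higher with IL4 at 0 of 4 dates. For miR-493-5p, a miRNA of the imprinted Dlk1-Dio3 region, it was -0.98 (SE 0.29, adjusted p = 0.243). The 10 most abundant lines (miR-21a-5p, let-7f-5p, let-7a-5p, miR-30d-5p, miR-26a-5p, let-7c-5p, miR-27b-3p, miR-203-3p, miR-92a-3p and miR-203b-5p) were not called. Of these lines only miR-21a-5p and the miR-203 lines were followed through the alternative fits. The miR-203 lines were called without a filter on low counts, and miR-21a-5p was called in no alternative.

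**Figure D1:**
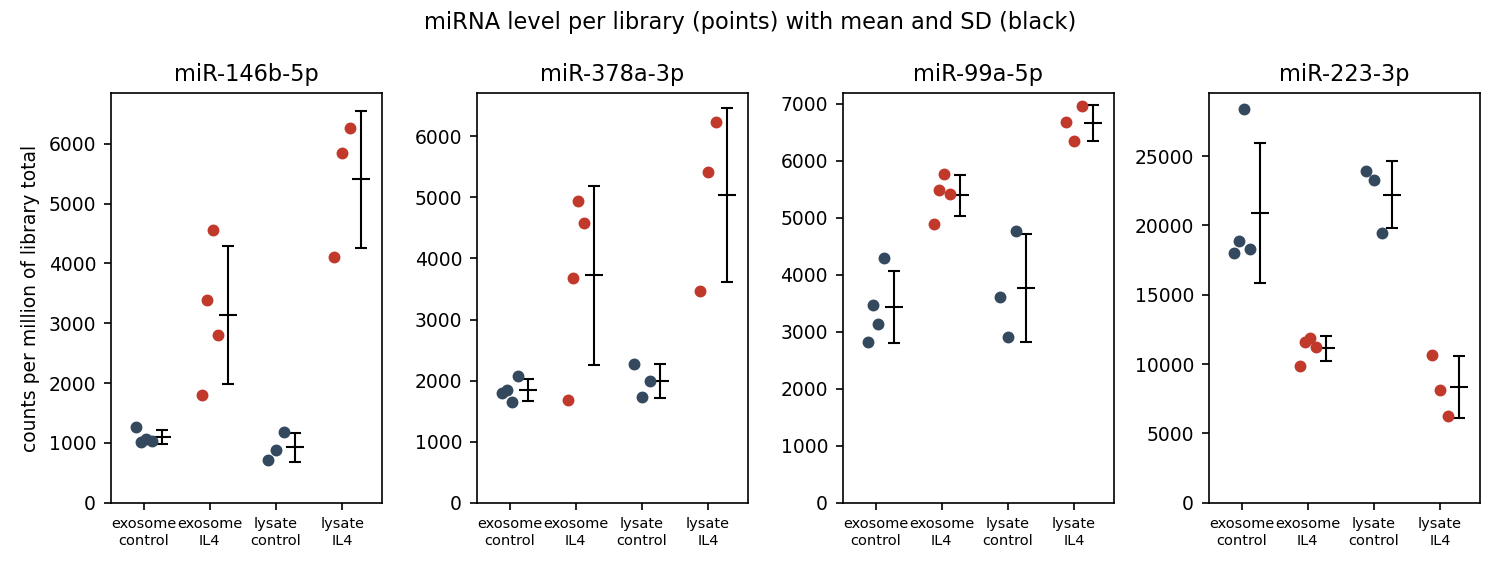
Levels of 4 miRNAs in CPM of the library total (y axes) in each library of the 4 groups (x axes); points are libraries and the black bars give the mean and SD. IL4 exosomes averaged 3136 CPM of miR-146b-5p against 1096 in control exosomes, and IL4 lysates 5406 against 925, whereas miR-223-3p averaged 8334 CPM in IL4 lysates against 22230 in control lysates.

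The study's own 4 miRNAs (miR-99a-5p, miR-146b-5p, miR-378a-3p and miR-33-5p) included 3 that could be tested in exosomes. Of these, 1 was called over all miRNAs tested and 3 when adjusted over the list alone, all higher with IL4, and the list shifted upwards against the other miRNAs (camera, adjusted p = 1.15e-07; adjusted p = 0.0521 with an estimated correlation). The study is known to have picked these miRNAs on these samples, so neither count is independent evidence. The fourth, miR-33-5p, which lies within Srebf2 and represses the cholesterol exporter Abca1, had 30 counts over the IL4 exosomes and 12 over the controls and was too low to test (88.9 ± 77.0 and 64.4 ± 73.5 CPM). The Dlk1-Dio3 list, miRNAs of an imprinted cluster active in progenitor and stromal cells, had 9 tested members, none with a positive log2 fold change and 0 called, by all miRNAs or adjusted over the list alone. Its shift was downwards (camera, adjusted p = 0.0261; adjusted p = 0.558 with an estimated correlation). Beside it, 0 of 4 tested erythroid marker miRNAs had a positive value and 0 were called (camera, adjusted p = 0.0676), with -0.99 for miR-144-3p and -0.54 for miR-451a. Erythroid markers took 2.51% of reads with IL4 against 4.01% in controls (exact permutation test, two-sided, p = 0.0571) and were higher with IL4 at 0 of 4 dates.

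Of 12 haematopoietic miRNAs, 2 had a positive log2 fold change and 0 were called over all miRNAs or over the list alone (camera, adjusted p = 0.0924); with the date as a block 1 was called higher and 2 lower over the list alone. Their share of reads was 3.70% with IL4 against 5.53% (exact permutation p = 0.0286, adjusted p = 0.210 over the lists; higher with IL4 at 0 of 4 dates). Among 7 miRNAs reported in released or circulating RNA, 0 were called over all miRNAs and 1 lower when adjusted over the list alone (camera, adjusted p = 0.0924). The IL4-reported list had 7 tested members and 0 calls over all miRNAs. Adjusted over the list alone, 1 was higher and 1 lower; its median was -0.08, its mean 0.06 and its direction in the test up (camera, adjusted p = 0.646). The list of the miR-99, let-7 and miR-125 clusters had 7 tested members and 0 calls; adjusted over the list alone, 1 was higher and 1 lower, with a median of -0.25 and an upward direction in the test (camera, adjusted p = 0.694). No call was made over all miRNAs or over the list alone among 5 inflammatory (camera, adjusted p = 0.562), 8 cholesterol-related (0.646), 10 miR-17/92-type (0.496), 9 let-7 (0.301), 8 miR-23/27/24 (0.126), 3 miR-221 and miR-222 (0.620), 5 stromal marker (0.646) or 3 liver, gut and serum marker miRNAs (0.301). With the date as a block, the calls over the list alone became 2 higher for miR-23/27/24, 1 lower for the inflammatory list, and 2 higher and 1 lower for the IL4-reported list and for the miR-99, let-7 and miR-125 clusters, with 0 calls over all miRNAs in each. The endothelial markers miR-126a-3p (-0.47, SE 0.50) and miR-126a-5p (-0.64, SE 0.46), the lymphocyte marker miR-150-5p (-0.46, SE 0.34), the muscle marker miR-1a-3p (-1.43, SE 0.75), miR-182-5p (0.86, SE 0.57) and miR-183-5p (0.36, SE 0.54) were not called. The epithelial miRNAs miR-203-3p (1.07, SE 1.49) and miR-205-5p (1.95, SE 1.79) were not called either; the miR-203 lines took 19.3% of IL4 exosome replicate 1 and 9.28% of control exosome replicate 1, both of 25 January. The read shares of endothelial, lymphocyte and stromal markers were higher with IL4 at 0 of 4 dates (exact permutation within dates, p = 0.125 for each, the smallest 4 pairs allow). Those of muscle and of liver, gut and serum markers were higher at 1 of 4 dates and that of epithelial markers at 2. The miR-378 family, with 1 tested member, and the Sfmbt2 cluster, with 0, were not tested as lists.

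At an unadjusted p under 0.05 there were 12 miRNAs. The call of miR-146b-5p ended without control replicate 2 (adjusted p = 0.0760), control replicate 3 (0.0552) or IL4 replicate 3 (0.0510), leaving 0 calls each time, and with scaling by library size (0.0890, the highest over its 20 alternatives, in which its log2 fold change ran from 1.52 to 1.98). There were 2 calls without control replicate 4, where miR-99a-5p passed (1.12, adjusted p = 0.0225), and 2 without IL4 replicate 1, where miR-378a-3p passed (1.42, adjusted p = 0.0253). DESeq2 called 6 miRNAs, among them miR-378a-3p, miR-99a-5p and miR-223-3p, and edgeR without a filter on low counts called 12.

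The second comparison asked how IL4 changed the miRNAs of the cells themselves. In lysates, miR-146b-5p rose 6.76-fold (log2 fold change 2.76, SE 0.32, adjusted p = 0.00754, 3 against 3 libraries), from 925 ± 244 to 5406 ± 1141 CPM. Along with it rose miR-378a-3p (1.58, SE 0.28, 2.99-fold), miR-511-3p, which lies within the gene of the mannose receptor Mrc1, an IL4-induced marker (1.42, SE 0.23, 2.68-fold), miR-125b-5p (1.30, SE 0.25, 2.46-fold) and miR-99a-5p (1.03, SE 0.22, 2.05-fold). The miRNA miR-146a-5p, the paralog of miR-146b-5p and like it a brake on NF-kB signalling, fell by 2.26 on the log2 scale (SE 0.44, adjusted p = 0.0224), from 2430 ± 1430 to 453 ± 184 CPM. Both arms of the miR-223 hairpin fell as well: miR-223-3p had a log2 fold change of -1.24 (SE 0.17, adjusted p = 0.00754), with 8334 ± 2220 CPM against 22230 ± 2425, and miR-223-5p one of -2.11 (SE 0.26).

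Among 443 miRNAs tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 26 rose and 6 fell, and each of these moved the same way at 3 of 3 dates. The other large rises were miR-9-5p, which is induced by inflammatory signals in myeloid cells (2.45, SE 0.54; 53.2 ± 34.0 against 11.8 ± 2.63 CPM), miR-7015-3p (1.77, SE 0.32), miR-149-5p (1.69, SE 0.35), miR-378a-5p (1.60, SE 0.35), miR-500-5p (1.34, SE 0.27) and miR-99a-3p (1.37). The other falls were miR-99b-3p (-1.43, SE 0.33), let-7e-5p (-1.32, SE 0.29) and miR-182-5p (-0.96, SE 0.23; 69.0 ± 20.2 against 152 ± 9.68 CPM). The miRNAs miR-21a-5p (0.63, SE 0.23, adjusted p = 0.220), miR-33-5p (0.32, SE 0.40, adjusted p = 0.858) and miR-155-5p, a driver of inflammatory activation (-1.06, SE 0.54, adjusted p = 0.463), did not pass, and neither did the other most abundant miRNAs let-7f-5p, let-7a-5p, miR-30d-5p, miR-26a-5p, let-7c-5p, miR-27b-3p, miR-222-3p, miR-221-3p and miR-23b-3p.

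Of the 4 study-named miRNAs, 3 rose, over all miRNAs tested and adjusted over the list alone (camera, adjusted p = 3.03e-05; adjusted p = 0.268 with an estimated correlation); these too were picked by the study on these samples. All 5 tested members of the miR-378 family had positive values, with 2 called over all miRNAs and 4 adjusted over the list alone (camera, adjusted p = 0.000648; adjusted p = 0.342 with an estimated correlation); the family's members are alike in sequence, so reads could be shared between them. Of 12 haematopoietic miRNAs, miR-181a-5p (0.76) and miR-181b-5p (0.92), known in lymphocyte development, rose, and miR-223-3p, miR-223-5p and miR-146a-5p fell, over all miRNAs and adjusted over the list alone (camera, downwards, adjusted p = 0.0420; adjusted p = 0.342 with an estimated correlation). No marker list was called beside these groups: the erythroid miR-451a had a value of -0.64 (SE 0.46, adjusted p = 0.745) and the lymphocyte miR-150-5p one of -0.12 (SE 0.47). The IL4-reported list had 11 tested members, of which 4 rose and 1 fell; adjusted over the list alone, 4 rose and 2 fell (camera, adjusted p = 0.114). It included miR-34a-5p (0.30) and let-7c-5p (0.33), which were not called. Of 13 inflammatory miRNAs, miR-9-5p and miR-21a-3p (1.16) rose and miR-146a-5p fell, with the same counts adjusted over the list alone (camera, adjusted p = 0.370).

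In the list of the miR-99, let-7 and miR-125 clusters, 4 of 12 tested members rose and 2 fell; adjusted over the list alone, 5 rose and 5 fell (camera, adjusted p = 0.879). Those that rose were miR-99a-5p, miR-99a-3p, miR-125b-5p and miR-125b-2-3p (1.20, SE 0.24), and those that fell were miR-99b-3p and let-7e-5p. Among miRNAs of the miR-500 to miR-532 cluster on chromosome X, 6 of 9 tested lines were called, all higher, among them miR-362-5p (1.05), miR-188-5p (1.19) and miR-532-5p (0.89). This cluster was not among the fixed lists and was singled out after its values were seen. The let-7 family had 10 tested members, with let-7e-5p the 1 that fell over all miRNAs and over the list alone (camera, adjusted p = 0.360). The released list had 7 tested members, of which miR-223-3p fell, by both adjustments (0.234). No call was made, by either adjustment, among 9 cholesterol-related (camera, adjusted p = 0.701), 17 miR-17/92-type (0.879), 11 miR-23/27/24 (0.877), 4 miR-221 and miR-222 (0.879), 24 Sfmbt2 cluster (0.613), 3 Dlk1-Dio3 (0.877), 8 stromal (0.547), 6 epithelial (0.360) or 4 liver, gut and serum miRNAs (0.879). Of miR-182-5p and miR-183-5p (-0.71, SE 0.23), tested as single miRNAs of their cluster, the first fell. The markers miR-126a-3p (-0.67, SE 0.35), miR-126a-5p (0.46, SE 0.35), miR-1a-3p (1.53, SE 0.54), miR-499-5p (-0.20, SE 1.32), miR-181c-5p (0.01, SE 0.33) and the joined line of miR-486a-5p and miR-486b-5p (-0.05, SE 0.25) were not called.

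**Figure D2:**
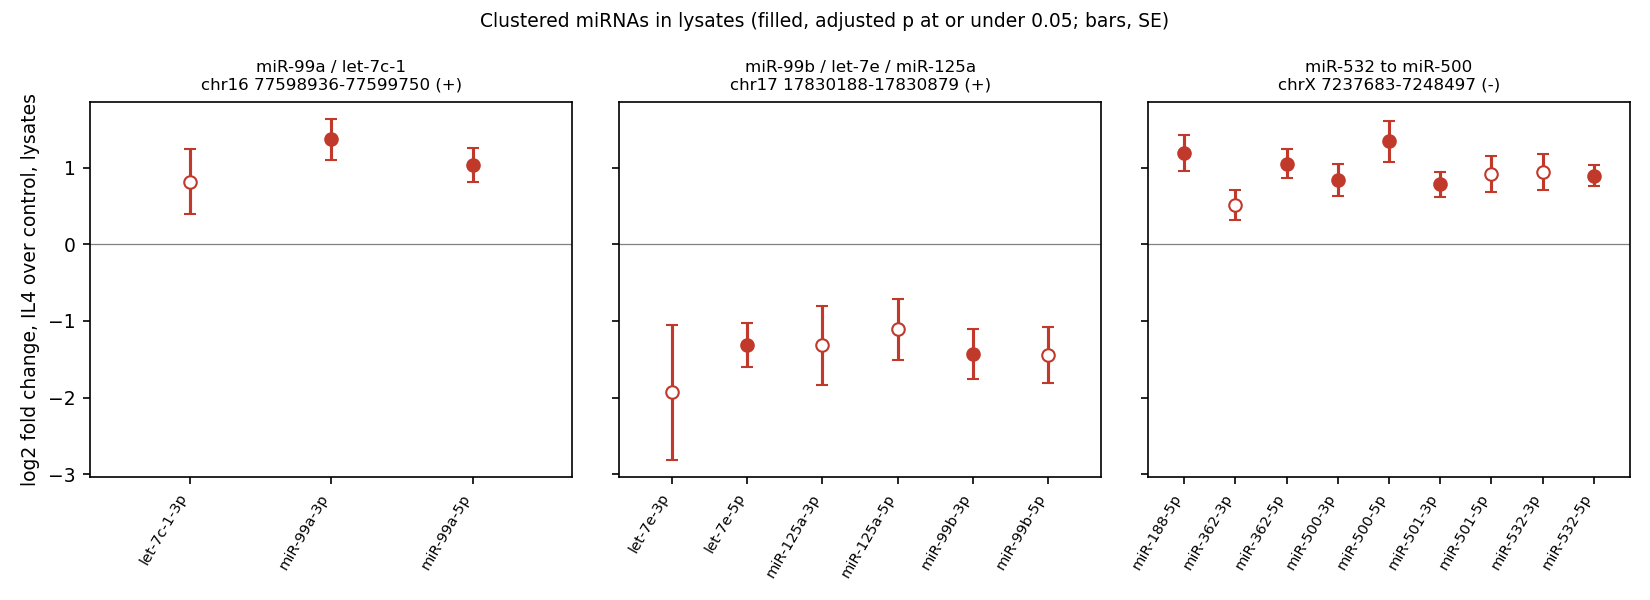
Log2 fold change of IL4 over control in lysates (y axis) for each tested miRNA (x axis) of 3 genomic clusters; bars are SE, and filled points have an adjusted p at or under 0.05. The 3 lines of the miR-99a cluster on chromosome 16 and the 9 lines of the chromosome X cluster lie above 0, and the 6 lines of the miR-99b cluster on chromosome 17 lie below it.

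With the date as a block, 38 miRNAs rose and 12 fell, 50 in all against 32, and all 32 were among them; the added ones included miR-21a-5p, miR-155-5p, miR-342-3p, miR-125a-5p and miR-99b-5p. Among the lists, the block gave 5 higher and 2 lower IL4-reported miRNAs (6 and 2 over the list alone), 3 higher in the miR-378 family (4 over the list alone), 3 higher and 2 lower inflammatory and 2 higher and 4 lower haematopoietic miRNAs (the same over these 2 lists alone), and 5 higher and 4 lower in the miR-99, let-7 and miR-125 clusters (6 and 6 over the list alone). Scaling by library size gave 8 higher and 6 lower and moved the median of all miRNAs by -0.19, and 1 fit over all 14 libraries gave 4 calls. The count was 2 without control replicate 2, 13 without control replicate 3, 7 without IL4 replicate 2 and 10 without IL4 replicate 3. The 2 miR-223 lines were called in all 17 alternatives (highest adjusted p = 0.0455), miR-146b-5p in all but 1 and miR-511-3p in all but 2. The other named calls ended more often, miR-9-5p in 8 of 17 (1.64 in place of 2.45 without IL4 replicate 3), miR-99a-5p, miR-149-5p and miR-182-5p in 7, miR-125b-5p, miR-125b-2-3p, miR-378a-5p, miR-500-5p and miR-99b-3p in 6, miR-378a-3p and let-7e-5p in 5, miR-7015-3p in 4 of 16 and miR-146a-5p in 3. Without control replicate 2 the miR-223 lines were the only calls.

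The genes of these miRNAs were located in the GRCm38 (mm10) build. Mir146b lies on chromosome 19, 46342762 to 46342870, plus strand, in an intron of Mfsd13a, with the 109-base hairpin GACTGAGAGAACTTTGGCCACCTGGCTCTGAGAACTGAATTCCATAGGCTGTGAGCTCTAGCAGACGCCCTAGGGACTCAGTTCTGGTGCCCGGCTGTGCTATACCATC. Mir378a lies on chromosome 18, 61397835 to 61397900, minus strand, in an intron of Ppargc1b, with the hairpin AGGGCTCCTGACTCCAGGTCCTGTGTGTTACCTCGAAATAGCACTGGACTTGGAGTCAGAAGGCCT. Mir99a lies on chromosome 16, 77598936 to 77599000, plus strand, in an intron of the noncoding host gene Mir99ahg, with the hairpin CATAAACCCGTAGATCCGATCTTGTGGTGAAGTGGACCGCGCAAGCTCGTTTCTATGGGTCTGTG. Mir125b-2 lies further along the same host gene, at 77646273 to 77646343; mature miR-125b-5p also comes from Mir125b-1 on chromosome 9, 41581926 to 41582002, and the counts do not separate these genes. Mir223 lies on chromosome X, 96242817 to 96242926, plus strand, in an exon of the noncoding gene F630028O10Rik, with the hairpin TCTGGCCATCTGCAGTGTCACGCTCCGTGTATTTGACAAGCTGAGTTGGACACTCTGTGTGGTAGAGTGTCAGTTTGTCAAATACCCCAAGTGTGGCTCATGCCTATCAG. Mir511 lies on chromosome 2, 14261003 to 14261081, plus strand, in an intron of Mrc1, Mir33 on chromosome 15, 82198122 to 82198190, plus strand, in an intron of Srebf2, and Mir149 on chromosome 1, 92850378 to 92850443, plus strand, in an intron of Gpc1. Mirlet7e lies on chromosome 17, 17830352 to 17830444, plus strand, in an intron of Spaca6, and Mir362 on chromosome X, 7241982 to 7242046, minus strand, in an intron of Clcn5.

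Exosomes and lysates of control macrophages were then compared, to ask how released miRNAs differ from those of the cells. Several miRNAs known as markers of other cell types were higher in control exosomes, although of the marker lists tested only the erythroid one was called. The erythroid miRNA miR-451a was at 24445 ± 5355 CPM in exosomes (n = 4) against 17.2 ± 7.58 in lysates (n = 3; log2 fold change 9.74, SE 0.56), and miR-126a-3p, the main endothelial miRNA, at 12766 ± 8599 against 26.7 ± 2.95 CPM (8.04, SE 0.67). The lymphocyte marker miR-150-5p (5.40, SE 0.59), the stromal marker miR-143-3p (3.92) and the muscle marker miR-1a-3p (8.64) were higher in exosomes as well. The macrophage-abundant miR-21a-5p was lower (-1.26, SE 0.25, adjusted p = 0.000735; -0.43 and not called when scaled by library size), as was miR-34a-5p, a p53-induced miRNA (-2.19, SE 0.27). Of the other most abundant miRNAs, let-7f-5p, let-7a-5p, let-7c-5p, miR-30d-5p, miR-27b-3p, miR-222-3p and miR-223-3p were lower on the TMM scale, and miR-26a-5p and miR-92a-3p were not called.

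Of 338 miRNAs tested, 99 were higher and 73 lower in control exosomes (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), with 193 at an unadjusted p under 0.05. These directions depend on the scaling: the median of all miRNAs was -0.18 with TMM, 0.22 with median-of-ratios factors (a shift of 0.39) and 0.63 by library size (a shift of 0.81), and the calls were 109 higher and 47 lower with median-of-ratios factors and 126 higher and 16 lower by library size, and 122 higher and 52 lower with DESeq2. Values are therefore also given relative to the median of all miRNAs. Some miRNAs had 0 counts in lysates, so that their ratio is given against a floor of 3 counts over the group. It is a lower bound for the lysate side only, as the exosome mean CPM carries its own spread. By that bound miR-205-5p, an epithelial miRNA, was at least 2059-fold higher, but at least 698-fold without control exosome replicate 1, and replicate 3 had 0 counts of it. The bound was at least 1369-fold for miR-7032-3p, 1350-fold for miR-153-3p (483-fold without replicate 4, and 0 counts in replicate 1), 1179-fold for miR-5110, 1042-fold for miR-219c-3p and 984-fold for miR-2183; without replicate 1 the last 3 were at least 584-fold, 542-fold and 606-fold. Without control lysate replicate 2 the floor rose and each bound was 1.60 times lower. Over the exosome libraries of both groups, the counts of some of these lines hardly grew with the library total. The slope of log2 counts on log2 total was -1.29 for miR-205-5p, -0.71 for miR-219c-3p, 0.34 for miR-2183 and 0.38 for miR-7032-3p. A count that does not follow the total gives a higher CPM in shallow libraries, which raises the mean CPM and the bound. Depth and date cannot be told apart here, as the deepest library of each exosome group was of 5 April. For miR-205-5p depth alone does not order the values. IL4 exosome replicate 1 (50032 counts in total) had 3738 CPM, whereas the shallower control exosome replicate 4 (36576) had 164. For miR-411-3p, with 1 lysate count, the ratio of pooled counts was 3119-fold (counting interval 537 to 125395). It was 1945-fold without control lysate replicate 2, and without replicate 1 the lysates held 0 counts. Its other arm miR-411-5p was at 824 ± 381 against 0.291 CPM (10.44, SE 0.82). The miR-203b-5p line (11.33, SE 2.26) was at 16791 ± 19597 CPM (10.34 without control exosome replicate 1), and it overlaps miR-203-3p on the opposite strand, so the reads of these lines may not be separable. On the lower side, miR-362-5p (-2.63, SE 0.47; 107 ± 84.3 against 391 ± 92.4 CPM) was lower. The other 9 of the 10 largest falls rested on 5 or fewer exosome counts. Those of the joined line of miR-669a-5p and miR-669p-5p (5 counts), miR-29a-5p (4) and miR-301b-3p (3) lay in control exosome replicate 3 alone and that of miR-27a-5p (1) in replicate 2 alone, so that without these libraries the exosomes held 0 counts and no fold is given. The rest were miR-3068-5p (-3.40), miR-467c-5p (-2.54, not called by library size), miR-3535, miR-29b-2-5p and miR-330-5p; the calls of miR-29b-2-5p (adjusted p = 0.0645) and miR-330-5p (0.0668) ended without control exosome replicate 3, and that of miR-330-5p also by library size (0.0822).

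All 19 tested Dlk1-Dio3 miRNAs were higher in control exosomes, among them miR-127-3p (7.10, SE 1.39), miR-379-5p (9.03) and miR-382-5p (7.98), by all miRNAs and adjusted over the list alone (camera, adjusted p = 1.03e-07; adjusted p = 0.302 with an estimated correlation). They took 1.05% of exosome reads against 0.00767% of lysate reads (exact permutation test, two-sided, p = 0.0286). The lysates of 23 January held less than the others, 0.000452% in the control and 0.000359% with IL4. The erythroid list was higher in 4 of 4 members by both adjustments, and its call held with an estimated correlation (camera, adjusted p = 8.71e-08; adjusted p = 0.0102 with an estimated correlation); it took 4.01% of exosome reads against 0.0163%. Besides miR-451a it holds miR-144-3p (8.50, SE 0.83), miR-144-5p (9.28) and the joined line of miR-486a-5p and miR-486b-5p (5.78, SE 0.39), which have 1 mature sequence. Of 7 tested released miRNAs, 5 were higher and 2 lower, by both adjustments (camera, adjusted p = 0.0215; adjusted p = 0.302 with an estimated correlation). The higher ones included miR-451a and miR-150-5p, which the marker lists also hold, together with the liver miRNA miR-122-5p (4.85, SE 1.45) and miR-320-3p (0.84), and the lower ones were miR-142a-3p (-0.82) and miR-223-3p (-0.89, SE 0.19). The let-7 family, a group of differentiation-associated miRNAs, was lower in 7 of 10 members by both adjustments, with 0 higher, led by let-7i-5p (-1.82, SE 0.25) and let-7f-5p (-1.79, SE 0.31) (camera, adjusted p = 0.0263; adjusted p = 0.603 with an estimated correlation). By library size 1 let-7 member was higher and 4 were lower, and relative to all miRNAs the family's median was -1.09 with TMM and -1.11 by library size.

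The miR-126a lines (miR-126a-5p, 8.94, SE 0.60) were the endothelial list, and both were higher. Of 7 stromal markers, 3 were higher and 2 lower; adjusted over the list alone, 4 were higher and 3 lower (camera, adjusted p = 0.641). The lower ones were miR-140-3p (-0.89) and miR-140-5p (-1.05). Muscle markers were higher in 3 of 3 members (0.134), epithelial in 2 of 5 (0.695) and liver, gut and serum markers in 2 of 3 (0.464), with 0 lower and the same counts adjusted over each list alone. Among haematopoietic miRNAs 1 of 12 was higher and 6 were lower (camera, adjusted p = 0.277), among them miR-16-5p (-0.84) and miR-15b-5p (-1.11), and the list's median was -0.62 relative to all miRNAs. The remaining lists were not called. Higher and lower counts were 0 and 2 of 4 study-named miRNAs (camera, adjusted p = 0.446), 2 and 5 of 11 IL4-reported (0.283), 1 and 4 of 9 inflammatory (0.368), 2 and 2 of 9 cholesterol-related (0.641), 1 and 3 of 15 miR-17/92-type (0.307), 1 and 2 of 10 in the miR-99, let-7 and miR-125 clusters (0.641), 0 and 4 of 11 miR-23/27/24 (0.134), 0 and 3 of 4 miR-221 and miR-222 (0.134) and 0 and 3 of 9 Sfmbt2 cluster miRNAs (0.134), the same when adjusted over each list alone. For the miR-17/92-type and the miR-99, let-7 and miR-125 lists the median (-0.37 and -0.28) and the mean (0.04 and 0.60) differed in sign. By library size the medians of the study-named, haematopoietic, miR-17/92-type and miR-99, let-7 and miR-125 lists turned positive, the last 2 also with median-of-ratios factors. The miR-378 family had 1 of 3 members lower over all miRNAs and 0 adjusted over the list alone (0.382), and 0 of 2 tested miRNAs of the miR-183 cluster were called.

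Of the study-named miRNAs, miR-146b-5p was not called in this comparison (-0.58, SE 0.34, adjusted p = 0.159; 0.24 by library size) except without a filter (-1.05, adjusted p = 0.0288), nor was miR-33-5p (1.63, adjusted p = 0.226). The call of miR-99a-5p (-0.93, adjusted p = 0.00586) ended without control exosome replicate 1 (-0.58, adjusted p = 0.0572), and its value was -0.60 without replicate 3 (adjusted p = 0.0469). It also ended with median-of-ratios factors (-0.52, adjusted p = 0.0741), by library size (-0.13, 0.734), with only the 2 groups in the fit (-0.68, 0.0540) and with thinned libraries (-0.47, 0.113). The call of miR-378a-3p (-0.89, adjusted p = 0.0375) ended with median-of-ratios factors (-0.49, adjusted p = 0.203), by library size (-0.12, 0.830), with DESeq2 (-0.50, 0.203), limma voom (-0.96, 0.0599) and thinned libraries (-0.60, 0.187), and without any 1 of control exosome replicates 1 (adjusted p = 0.147), 2 (0.0597) and 3 (-0.57, 0.196) or control lysate replicates 1 (0.0539), 2 (0.0676) and 3 (0.0826). Thinned to equal totals, 41 miRNAs were higher and 15 lower of 148 tested. No date held both compartments, so exosomes and lysates could not be compared within a date, and the spread between dates is part of the spread between replicates.

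**Figure D3:**
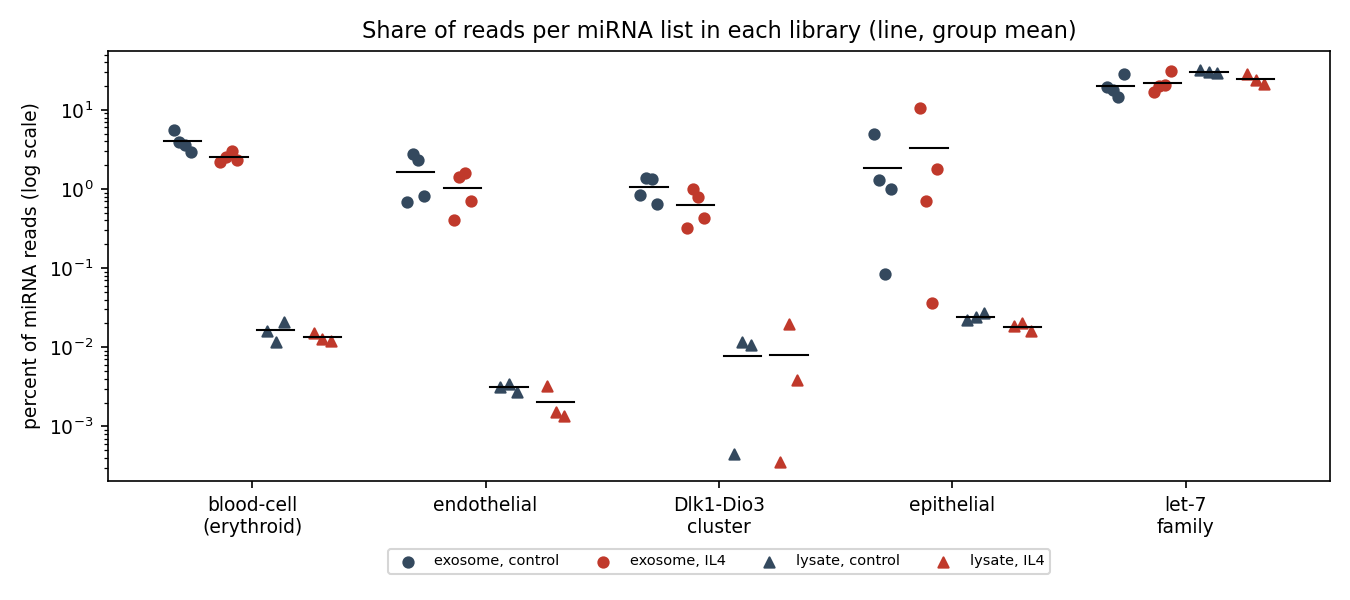
Share of miRNA reads, in percent on a log scale (y axis), taken by 5 fixed lists (x axis) in each library; circles are exosomes, triangles lysates, and the lines are group means. Erythroid markers averaged 4.01% in control exosomes and 2.51% in IL4 exosomes against 0.0163% and 0.0133% in the lysates, while the let-7 family averaged 20.1% and 22.1% against 30.4% and 24.5%.

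The same comparison was made for IL4-stimulated macrophages. Erythroid miR-451a was at 15202 ± 2958 CPM in IL4 exosomes (n = 4) against 9.44 ± 5.29 in IL4 lysates (n = 3; log2 fold change 9.93, SE 0.56), and the endothelial miR-126a-3p at 8124 ± 4396 against 15.1 CPM (8.43, SE 0.68). The lymphocyte miR-150-5p (5.20, SE 0.58) and miR-10b-5p, encoded in a Hox gene cluster (8.89), were also higher in exosomes. Of the miRNAs that rose with IL4 in lysates, miR-146b-5p (-1.56, SE 0.33, adjusted p = 0.00154), miR-511-3p (-3.11, SE 0.63; 41.7 ± 48.9 against 259 ± 71.1 CPM) and miR-500-5p (9 exosome counts, all in IL4 exosome replicate 3) were lower. So were miR-21a-5p (-1.38, SE 0.25) and miR-34a-5p (-2.43, SE 0.27; 400 ± 56.0 against 1328 ± 62.5 CPM). Of the other most abundant miRNAs, let-7f-5p, miR-30d-5p and miR-222-3p were lower on the TMM scale, and let-7a-5p, let-7c-5p, miR-26a-5p, miR-27b-3p and miR-92a-3p were not called.

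Of 338 miRNAs tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 30.2% were higher and 19.2% (65 miRNAs) lower. The lower count was 40 without IL4 lysate replicate 1, 32 without replicate 2 and 43 without replicate 3. By library size the split was 128 higher and 12 lower, and the median of all miRNAs moved from -0.01 to 0.68 (a shift of 0.70; 0.30 with median-of-ratios factors and -0.15 with upper quartiles). Against the floor of 3 counts over the lysates, miR-205-5p was at least 5082-fold higher, but at least 574-fold without IL4 exosome replicate 1, which held 187 of its 215 counts. As in controls, such bounds cover the lysate side only, and the exosome mean CPM carries its own spread. The bound was at least 2522-fold for miR-411-5p (507 ± 205 CPM in exosomes), 1824-fold for miR-5108 (1139-fold without replicate 1), 826-fold for miR-153-3p, 671-fold for miR-7032-3p, 574-fold for miR-411-3p, 556-fold for miR-219c-3p (288-fold without replicate 4) and 488-fold for miR-381-3p. Without IL4 lysate replicate 1 or 3 the floor rose and each bound was 1.64 or 1.52 times lower. Over the exosome libraries of both groups, miR-5108 had 17 to 39 counts (slope of log2 counts on log2 total -0.06) and miR-7032-3p 3 to 20 (0.38). These counts hardly grew with the library total, so the bounds lean on the shallow libraries. The deepest library of each exosome group was of 5 April, so depth and date cannot be told apart here. The miR-203-3p line was at 31273 ± 46678 CPM against 12 (10.91) and miR-203b-5p gave 13.00 (SE 2.41); without IL4 exosome replicate 1 these values were 8.78 and 10.96. Lower lines included miR-3535 (2 exosome counts), miR-3068-5p (-3.27), the joined line of miR-669a-5p and miR-669p-5p (-2.51, -3.40 to -1.97 with 1 library left out; 14 of its 16 exosome counts in IL4 exosome replicate 3), miR-467c-5p (-2.41), miR-467e-5p (-2.63), miR-29b-2-5p (-2.29) and miR-350-5p (-2.03), of which the last 4 were not called by library size. These rested on 2 to 16 exosome counts, all of miR-29b-2-5p's 11 in IL4 exosome replicate 3.

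All 19 tested Dlk1-Dio3 miRNAs were again higher, with 6.46 for miR-127-3p and 8.52 for miR-379-5p, by both adjustments (camera, adjusted p = 1.44e-07; adjusted p = 0.400 with an estimated correlation), as were all 4 erythroid lines (camera, adjusted p = 2.68e-08; adjusted p = 0.0303 with an estimated correlation), among them miR-144-3p (7.62), miR-144-5p (9.33) and the miR-486 line (5.50). Of 7 released miRNAs 5 were higher and 1 was lower by both adjustments (camera, adjusted p = 0.00564; adjusted p = 0.198 with an estimated correlation). The endothelial miR-126a-5p was higher (7.98, SE 0.58). Stromal markers were higher in 4 of 7 members and lower in 0, with 1 lower when adjusted over the list alone (camera, adjusted p = 0.533), among them miR-143-3p (3.50) and miR-214-3p (3.49). Muscle markers were higher in 2 of 3 (0.303), epithelial in 2 of 5 (0.719) and liver, gut and serum markers in 1 of 3 (0.672), with 0 lower, by both adjustments. Both miR-182-5p (1.84) and miR-183-5p (1.76) were higher. In the let-7 family let-7b-5p (0.62) and let-7e-5p (1.15) were higher and 5 of 10 members lower, among them let-7i-5p (-1.48) and let-7f-5p (-1.06), by both adjustments (camera, adjusted p = 0.164); by library size 2 were higher and 2 lower, and relative to all miRNAs the median was -0.78 with TMM and -0.81 by library size.

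Higher and lower counts in the other lists were 0 and 3 of 4 study-named miRNAs (1 and 3 adjusted over the list alone; camera, adjusted p = 0.278), 3 and 3 of 11 IL4-reported (0.194), 0 and 1 of 3 in the miR-378 family (0.294), 1 and 3 of 9 inflammatory (0.331), 2 and 1 of 9 cholesterol-related (0.508), 2 and 5 of 12 haematopoietic (0.417), 1 and 6 of 15 miR-17/92-type (0.164), 3 and 2 of 10 in the miR-99, let-7 and miR-125 clusters (0.769), 0 and 2 of 11 miR-23/27/24 (0.276), 0 and 3 of 4 miR-221 and miR-222 (0.169) and 0 and 3 of 9 Sfmbt2 cluster miRNAs (0.164). Except for the study-named list these counts were the same adjusted over each list alone. The haematopoietic median was -0.48 with a mean of 0.13, and the miR-99, let-7 and miR-125 median was 0.19 with a downward direction in the test. By library size the medians of the IL4-reported, haematopoietic, miR-17/92-type, miR-23/27/24 and Sfmbt2 lists turned positive and that of the inflammatory list changed sign, as it also did with median-of-ratios factors.

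The call of miR-378a-3p (-1.22, adjusted p = 0.00744) ended without IL4 lysate replicate 2 (-0.93, adjusted p = 0.0574) or 3 (-0.80, 0.0917), by library size (-0.43, 0.308) and with thinned libraries (-0.76, 0.0841). That of miR-500-5p (adjusted p = 0.0118) ended without IL4 lysate replicate 2 (0.0555) and by library size (0.0673), and without IL4 exosome replicate 3 its exosome count was 0. Those of miR-467e-5p, miR-467c-5p, miR-29b-2-5p and miR-350-5p each ended without IL4 exosome replicate 4 (adjusted p = 0.0771, 0.0537, 0.0550 and 0.0871). Without IL4 exosome replicate 2 the calls of miR-467e-5p (0.0652), miR-29b-2-5p (0.0541) and miR-350-5p (0.0652) ended, and without replicate 1 that of miR-350-5p (0.0754); that of miR-467e-5p also ended without IL4 exosome replicate 3 (0.0623) and without IL4 lysate replicate 2 (0.0771) or 3 (0.101) and with limma voom (0.0521), and that of miR-350-5p with median-of-ratios factors (0.0616), without a filter (0.0584) and without the miR-203 lines (0.0566). The call of miR-99a-5p (adjusted p = 0.00417) ended by library size alone (adjusted p = 0.308), and miR-33-5p (2.26, adjusted p = 0.0807) was called without IL4 exosome replicate 2 (0.0457) or 3 (0.0316), by library size (0.0362) and with DESeq2 (0.0202). Thinned to equal totals, 45 miRNAs were higher and 20 lower.

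The genes of the miRNAs higher in exosomes were located in the same build. Mir451a lies on chromosome 11, 78073170 to 78073241, plus strand, between genes, with the hairpin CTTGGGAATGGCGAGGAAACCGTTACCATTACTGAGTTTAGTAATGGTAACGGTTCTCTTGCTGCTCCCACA, beside Mir144 at 78073005 to 78073070. Mir126a lies on chromosome 2, 26591357 to 26591429, plus strand, within Egfl7, where it overlaps an exon of at least 1 annotated transcript and may be intronic in others. Mir411 (chromosome 12, 109710175 to 109710256) and Mir127 (109592846 to 109592915) lie in the Dlk1-Dio3 region, plus strand. Mir150 lies on chromosome 7, 45121757 to 45121821, and Mir205 on chromosome 1, 193507463 to 193507530, minus strand, in an exon of the noncoding gene 4631405K08Rik.

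The last comparison asked whether the IL4 effect differed between exosomes and lysates. No miRNA was called among 338 tested with edgeR's quasi-likelihood test (0 calls, 14 at an unadjusted p under 0.05); DESeq2 called 0 with 22 and limma voom 0 with 14 at that level. For miR-146b-5p the exosome effect minus the lysate effect was -0.98 (SE 0.48, adjusted p = 0.995), for miR-378a-3p -0.33 (SE 0.48), for miR-99a-5p -0.08 (SE 0.35) and for miR-33-5p 0.63 (SE 1.44). The lowest unadjusted p belonged to miR-100-5p (-4.00, SE 1.19), miR-223-5p (1.69, SE 0.52), miR-182-5p (2.02, SE 0.71), miR-27a-5p and miR-8095, each with an adjusted p of 0.857; without a filter miR-100-5p was called (-3.68, adjusted p = 7.26e-06). No value is given for miR-27a-5p, with 1 count over the control exosomes, or for miR-8095, with 0 counts over the control lysates. The most abundant miRNAs (miR-21a-5p, let-7f-5p, let-7a-5p, miR-30d-5p, miR-26a-5p, let-7c-5p, miR-27b-3p, miR-92a-3p, miR-222-3p and miR-23a-3p) were not called in this comparison. Of 19 lists tested, the muscle markers, with 3 tested members and 0 called, shifted downwards (camera, adjusted p = 0.0284; adjusted p = 0.443 with an estimated correlation). The miR-99, let-7 and miR-125 list had 0 calls over all miRNAs and 1 lower adjusted over the list alone. In simulated data this test recovered 8% of 4-fold differences among the changed lines that passed the filter. Its count of 0 therefore leaves differences of that size open.

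Across the 162 miRNAs tested in both compartments, the IL4 effects in exosomes and in lysates, which share no library, had a Pearson r of 0.295 (permutation p = 0.00034) and a Spearman rho of 0.301 (permutation p = 0.00014), and 62.3% had the same sign; miRNAs are not independent replicates. Of the miRNAs that rose in lysates and were tested in exosomes, 10 of 10 had a positive value there, and of those that fell 4 of 5 had a negative one. The exception was miR-182-5p (-0.96 in lysates and 0.86, SE 0.57, in exosomes). The 1 exosome call, miR-146b-5p, was also a lysate call (0.0617 shared calls would come from independent lists).

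**Figure D4:**
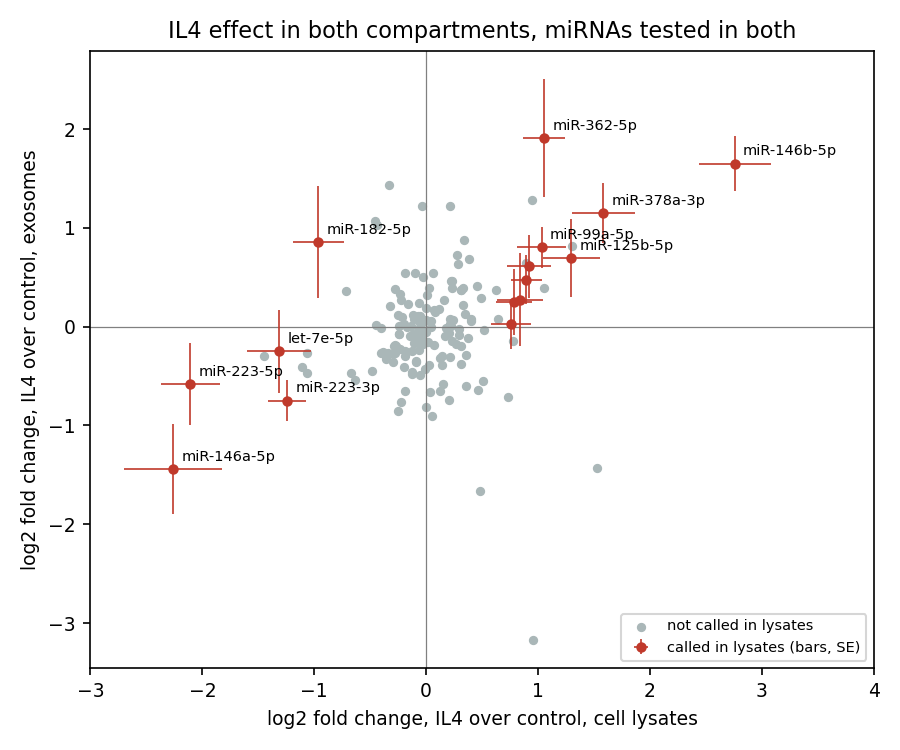
Log2 fold change of IL4 over control in exosomes (y axis) against that in lysates (x axis) for the 162 miRNAs tested in both; red points were called in lysates and carry SE bars. The 10 miRNAs that rose in lysates lie above 0 in exosomes, with miR-146b-5p at 2.76 and 1.65, and 4 of the 5 that fell lie below it.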

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

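The tests of explanations in this part and the counts of other sample splits were chosen after the results they address had been seen.

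In groups of 4 libraries, values were screened for 1 library far from the rest, by the gap to its nearest neighbour as a fraction of the group's range. Of 127 such groups 8 lay above Dixon's critical value at the 95% level, and chance alone gives about 1 in 20 (5%). Total counts set replicate 3 of 5 April apart in IL4 exosomes (411671 against 50032 to 76729, gap fraction 0.926) and in control exosomes (199025 against 28417 to 54381, 0.848). In IL4 exosomes, replicate 1 of 25 January stood apart in the share of cholesterol-related miRNAs (8.14% against 5.23% to 5.65%, 0.857), in the share of epithelial markers (10.5% against 0.0360% to 1.81%, 0.830) and in miR-205-5p (3738 CPM against 4.86 to 248, 0.935). In control exosomes, replicate 4 of 29 December stood apart in the share of lymphocyte markers (0.0684% against 0.171% to 0.187%, 0.867) and in let-7c-5p (39151 CPM against 17414 to 20711, 0.848), and replicate 3 in miR-223-3p (28403 CPM against 17982 to 18904, 0.912).

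The named and listed miRNAs were scanned for IL4 effects that pointed opposite ways in the compartments at every date, and a pair was found. A scan of many miRNAs turns up some such cases by chance, and the number to be had by chance was not worked out. miR-100-5p was lower with IL4 at all 4 exosome dates (600, 308, 1183 and 117 CPM against 12352, 1030, 1266 and 6671) and higher at all 3 lysate dates (16.9, 21.8 and 24.3 against 11.1, 12.2 and 14.3), a difference of effects of -4.00. miR-126a-5p was lower with IL4 at the 4 exosome dates and higher at the 3 lysate dates (6.83, 4.82 and 4.09 CPM against 4.69, 4.42 and 3.81), a difference of -0.96. The lysate differences of miR-126a-5p were small, and its other arm miR-126a-3p had a negative log2 fold change in lysates (-0.67). The opposite directions were not tested as such, and the difference of effects was called for neither miRNA (adjusted p = 0.857 for miR-100-5p, edgeR's quasi-likelihood test), although without a filter on low counts miR-100-5p was called (-3.68, adjusted p = 7.26e-06).

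Blood-cell, endothelial and Dlk1-Dio3 miRNAs stood far higher in exosomes than in lysates, in 25 lines. A source of 1 fixed composition is argued against by the ratio of miR-126a-3p to miR-451a, which differed 5.50-fold between libraries of 25 January and 16 March (0.167, 95% interval 0.139 to 0.199, and 0.917, interval 0.847 to 0.992, in the controls). The ratio in IL4 and control exosomes matched by date better than in any other of 24 pairings (exact permutation p = 0.0417, the smallest that 24 pairings allow). A source that changes with the date, such as serum or vesicles of other cells, may contribute. Same-date libraries also deviated together over all miRNAs, however, so the match cannot tell such a source from other differences between dates. An amount added with reagents, which would need the RNA input (not given in the sources used here), and release by the macrophages themselves were not tested and stay open.

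The lines of miR-203-3p and miR-203b-5p took 143016 CPM in the exosome libraries of 25 January and 801 CPM in those of 5 April. A fixed count per library, as from reagents, is argued against: their summed counts ran from 134 (95% counting interval 112 to 159, in the deepest exosome library) to 9668, and the lower count of 25 January (2637, interval 2537 to 2740) was 10.4 times the higher of 5 April (254, interval 224 to 287); an amount that differs between libraries, or is diluted by differing RNA input, was not tested and stays open. Epithelial cells as a candidate source would bring the miR-200 family too, which was 3.32-fold higher at 25 January (588 against 177 CPM; 1.79-fold without the IL4 library of 25 January, which held 43 counts of it, and 4.86-fold without the control), while the miR-203 lines were 179-fold higher and miR-205-5p stood at 2379 against 2.43 CPM. The proportion of these miRNAs in such cells is not given in the sources used here, so epithelial cells cannot be told apart from other sources. Beyond these candidate sources no biological explanation was tested; the ratio of miR-203b-5p to miR-203-3p was 0.654 to 0.988 in exosomes and 0.111 to 0.380 in lysates, and their genes overlap on chromosome 12 (112130880 to 112130955 and 112130887 to 112130946).

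In exosomes, 3 of the 35 splits of the 8 libraries, the real one included, gave at least the 1 call of IL4 against control, with 2 as the highest other, so chance cannot be excluded for that count. A split of 29 December and 25 January, the earliest exosome dates, against the other dates also gave 1 call, as did the date-blocked fit of the real groups. Among the 8 splits that part every date the highest other was 0, and among the 27 that do not it was 2. In lysates the 10 splits are too few for a share under 0.05; the real split gave 32 calls (1 split as large, itself) and the highest other 0, both among the 4 that part every date and among the rest. For exosomes against lysates in controls, the real split alone (1 of 35) gave as many calls, 172 against 69 for the highest other. In IL4 libraries it was also alone (1 of 35), with 49.4% of the 338 miRNAs tested called against 34 miRNAs for the highest other. A share of 1 of 35 is the smallest these splits can give, so it argues against chance for these counts but does not exclude it. For the difference of effects the real count was 0, which all 100 splits, the real one included, reach, so this decides nothing; the highest other gave 4.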

How the results depend on the processing

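Chosen after seeing the data were the fits without the miR-203 lines, without both exosome libraries of 25 January, without both lysate libraries of 23 January and with all libraries thinned, the list calls under each scaling, the tests of depth, detected miRNAs and minor-arm share within dates, and the leave-one-out values of depth, detected miRNAs, minor-arm share, the agreement of effects, the lower bounds and the miR-200 fold. Over 86 pairs of a named miRNA and a comparison, 1521 alternative values were computed: 1356 kept their direction and their side of the threshold, 130 lost the call, 17 gained one and 18 changed sign. Where no cause is given, the cause was not tested. Depth limited which miRNAs could be tested: exosome totals of 28417 to 411671 counts left 14.6% of lines to test, where 443 miRNAs were tested in lysates.

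The count of calls for IL4 in exosomes (1) was 0 by library size, 12 without a filter on low counts and 6 with DESeq2, and 0 to 2 with 1 library left out. In lysates the 32 calls became 14 by library size, 4 with all 14 libraries in 1 fit and 2 to 34 with 1 library left out; the replicate block by date gave 50. The block also changed calls over lists, which are given with each comparison, and no other call. Thinned to the smallest total, exosomes against lysates gave 56 calls in controls and 65 with IL4, with fewer reads and miRNAs tested. The difference of effects gave 3 calls without a filter. Other alternatives left these counts, of both directions together, within 1.5 times of their main values.

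The lists called by camera were 2 for IL4 in exosomes, 3 in lysates, 4 and 3 for exosomes against lysates in control and IL4, and 1 for the difference of effects. With an estimated correlation they were 0, 0, 1, 1 and 0, and with fry, which does not compare a list with other miRNAs, 1, 4, 13, 13 and 0. With the date block the lists called by camera were unchanged, whereas fry called the haematopoietic list in exosomes (adjusted p = 0.0414 against 0.186) and ended the study-named one (0.0644 against 0.0215), and in lysates it ended its 4 calls (study-named 0.0726, IL4-reported 0.107, miR-378 family and haematopoietic 0.191 each).

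Lines with at least 10 counts without thinning gave differences opposite to the thinned ones: 29.25 for IL4 in exosomes, -285.25 for exosomes against lysates in controls and -219 with IL4, in the order of the totals. The share of reads from the lower arm was higher in exosomes than in lysates in controls (4.39% against 2.37%, exact permutation p = 0.0286) and with IL4 (3.69% against 1.90%, p = 0.0571), but its median over arm pairs was lower (-2.75 and -2.37 points); for IL4 in exosomes the median gave 0.0638 in place of -0.70. With 1 library left out, the difference in total count ran from -12464.08 to 113478.2 for IL4 in exosomes, from -6191883.8 to -5551688.2 for exosomes against lysates in controls and from -5341746 to -4386070.5 with IL4. Detected miRNAs differed by 83.0 to 96.2 in controls and 76.6 to 91.4 with IL4, and the lower-arm share by 1.79 to 2.22 points in controls; these tests passed the threshold less often because fewer libraries cannot give a p under 0.05.

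For IL4 in exosomes, miR-203-3p changed sign with limma voom (-0.031) and ran from -0.96 without IL4 replicate 1 to 2.66 without control replicate 1. miR-203b-5p changed sign with voom (-0.20) and with the date block (-0.061), and ran from -0.94 to 2.58 without these same libraries. For exosomes against lysates in controls, miR-146b-5p was 0.24 by library size, which shifts all miRNAs upwards. In the difference of effects, none of them called, miR-33-5p ran from -0.25 to 1.99 with 1 library left out, miR-378a-3p from -0.52 to 0.082 (0.013 without IL4 exosome replicate 1) and miR-99a-5p from -0.27 to 0.18, with 0.14 without a filter and 0.032 without the miR-203 lines.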

Other observations

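The tests in this part were chosen after the values had been seen. Neighbouring miRNA genes moved together under IL4 in lysates. On the X chromosome (7237683 to 7248497, minus strand, within Clcn5), all 9 tested lines of 5 hairpins were higher, with 6 called and log2 fold changes from 0.51 to 1.34. On chromosome 16 (77598936 to 77599750) the 3 lines that match miR-99a or let-7c-1 alone were higher with 2 called. They leave out let-7c-5p, which more than 1 gene makes and which was not called. On chromosome 17 (17830188 to 17830879) the 6 lines of miR-99b, let-7e and miR-125a were lower with 2 called, with a median of -1.37. On chromosome 6 (30165918 to 30169737) miR-182-5p and miR-183-5p were lower with 1 called.

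The set of miRNAs that were higher in exosomes than in lysates in control and in IL4 samples held 90 miRNAs, where independent lists of these sizes would share 29.9, and 51 were lower in both, where 14.0 would be shared; the comparisons share no library but come from 1 fit. Among the 90, 68 had at least 50 exosome counts, and their counts grew with the library total with a median log-log slope of 1.06. For 15 of them, among them miR-205-5p, miR-203-3p, miR-219c-3p and miR-100-5p, the slope was under 0.5, in 9 also with each date left out.

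The miR-99a and miR-99b clusters were singled out because their lines moved apart in lysates, so values from these libraries restate that. The log2 ratio of the miR-99a to the miR-99b cluster there was 2.68 higher with IL4 for the other arms and 2.57 higher for the main arms without let-7 (exact permutation p = 0.1 for each, the smallest possible with 3 against 3 libraries). In exosomes, which share no library with the lysates, the ratio for all main arms was 0.90 higher (exact permutation p = 0.0286, 4 of 4 dates) and 1.15 higher without let-7 (p = 0.0286, 4 of 4 dates), but for the other arms the difference of 1.27 did not pass (exact permutation p = 0.2, 3 of 4 dates, groups overlapping). The main-arm ratios include miR-99a-5p, which the study picked on these samples, so the exosome values are not independent of that choice. Whether reads shared between the near-identical main arms bear on these ratios was not tested.

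If IL4 acts before the arms of a hairpin are separated, both arms should move alike. Across 114 hairpins in lysates the log2 fold changes of the arms had a Pearson r of 0.837 and a Spearman rho of 0.643 (permutation p = 1e-05 for each, the smallest that 100000 permutations can give), and 84 had the same sign; hairpins are not independent replicates. In 31 genomic clusters of 88 hairpins, neighbours differed by a mean of 0.232 in log2 fold change against 0.545 with permuted hairpins (permutation p = 0.0001, the smallest possible with 10000). Changes in the primary transcripts, which may reflect transcription, would give both results, but the primary transcripts were not measured. Arms and neighbours were read in the same lysate libraries, so any difference in hairpin level between these libraries would also make them move alike. The permutations therefore cannot tell an effect of IL4 from such differences.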
